A study of Rattus norvegicus with 12 samples.

How the data were processed

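Total RNA from 12 cultures of neonatal rat SKPs was labelled with biotin and hybridised to 1-colour Affymetrix Rat Gene 2.0 ST arrays, per the labels' protocols. The deposited values are log2 expression values per feature of the array, made by the authors with oligo and RMA, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of a feature. Versions, settings and the array annotation are not given in the sources used here. Such normalization sets the arrays to a common distribution, so that a change in total RNA per cell is not visible in these values. The values had 36685 features and a column for each of the 12 arrays.

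Groups and replicate numbers came from the sample titles. The 4 groups had 3 arrays each, and no pair of arrays held the same values. Symbols came from the platform annotation supplied for the array: 18511 features had 1 gene symbol, 575 had several and 17599 had none. Features with several or none were left out of the tests. Symbols were updated through Entrez identifiers to the GRCr8 gene table, which held 18394 of the 18511, and the other 117 kept the annotation's symbol. Coordinates are not given because the build of the array annotation is not named. For symbols with several features (636 features) the brightest on average was used, which left 18166 genes. Genes with a mean log2 value under the 25th percentile of the features with a symbol, 5.83, were left out, and 13636 were tested.

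One limma model (limma 3.58.1 in R 4.3.3) was fitted to all 12 arrays with a mean per group, so that the groups share 1 estimate of the spread with 8 residual degrees of freedom. Contrasts were tested with lmFit, contrasts.fit and eBayes, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 within each contrast. A moderated F test compared the 4 groups. Before the data were examined, 28 gene lists were fixed, which cover pathways of the drugs (MEK and ERK output, MAP kinase cascade, receptor tyrosine kinases, cyclic AMP and CREB targets, prostanoid receptors and metabolism, opioid receptors and ion channels), the cell cycle (DNA replication, mitosis, p53 targets and senescence), the dermal lineage and wound repair (dermal precursor and neural crest, dermal papilla, extracellular matrix, smooth muscle and myofibroblast, wound growth factors and proteases), markers of other cells (Schwann and neural, melanocyte, keratinocyte, adipocyte, endothelial, macrophage and leukocyte) and other programmes (cholesterol synthesis, glycolysis and hypoxia, ATF4 and unfolded protein response, interferon, BMP and SMAD, Wnt, Notch, housekeeping). Each was tested with limma's camera at its preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 28 lists, and again with an estimated correlation and with fry. These last tests were run without the replicate block described below, so differences between replicate numbers enter the estimated correlation. The comparisons, the rule for naming genes and the alternatives were fixed at the same time.

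Named genes were the 10 largest rises and 10 largest falls per comparison among genes that passed and whose groups did not overlap, without locus-number names and olfactory or vomeronasal receptors. Where fewer than 5 passed in a direction, the smallest p-values filled up to 5. Up to 4 members per list with the smallest p were added, and the genes of the drug targets. Members named beyond these, such as those listed as rising or falling with no value, complete a count of a list and were chosen after their values were seen.

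The labels give each group the same replicate numbers, and the design text speaks of 3 independent isolates. All 18 pairs of arrays with the same number deviated together from their group means (r from 0.21 to 0.81), and the 36 pairs with different numbers had r from −0.71 to 0.10. All 12 arrays were closest to their own number in every other group, so the numbers were taken to pair the samples. The replicate block was an alternative fit, with 6 residual degrees of freedom, and values from it are given beside results. Counts, calls and runs without an array come from the fit without the block unless the block is named. In that fit differences between replicate numbers count as spread, and the median SE was 0.0867, beside 0.0722 with the block. Genes said not to pass may therefore pass with the block. The p-values measure the spread between cultures of these isolates.

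The steps were tested on simulated data made from the spread of the real genes, with 13636 genes. For alprostadil against vehicle, 88% of 50 genes changed by 0.5 on the log2 scale were recovered, and 100% of those changed by 1, 2 or 3, with 9 false among 206 calls. For trimebutine with trametinib against trimebutine, 70% were recovered at 0.5, 98% at 1 and 100% at 2 and 3, with 6 false among 194 calls. Both simulations used the same spread with other genes drawn, so 88% and 70% do not set the comparisons apart. The noise was independent between genes and arrays, with no effect of the replicate number. These shares may therefore not hold for the real arrays. The alternatives were other low-signal limits, all features, the mean of a gene's features, quantile normalization again, median centring, a trend and robust fit, array weights, the replicate block, only the 6 arrays compared, other thresholds, the other list tests and each array left out in turn. Correlations of fold changes were set beside 100 simulations of unchanged groups, drawn with the spread of the blocked fit.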

Results

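Gene expression was measured in skin-derived precursors (SKPs), which are dermal stem or precursor cells that grow as floating spheres, isolated from newborn Sprague-Dawley rats. Cells from dissociated spheres were cultured for 24 h with vehicle, 100 nM alprostadil, 100 nM trimebutine maleate, or 100 nM trimebutine maleate together with 100 nM trametinib. Alprostadil is prostaglandin E1, trimebutine is a gut motility drug that acts on opioid receptors and ion channels, and trametinib inhibits MEK, the kinase that activates ERK. The series title names a screen for drugs that enhance skin repair. Each of the 4 groups had 3 arrays, for 12 arrays in all, from 3 independent isolates of cells. The deposited log2 values had medians from 6.409 to 6.505 across arrays, and arrays of a group correlated at 0.985 to 0.991. Alprostadil replicate 1 had the highest median. The number of arrays limits the precision. After low signals were left out, 13636 genes were tested. Values are differences of mean log2 values with the standard error (SE) of the fit, with n = 3 arrays per group, and adjusted p-values are from limma unless another test is named.

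The comparison of alprostadil with vehicle asked which genes a prostaglandin drug changes in these cells. Alprostadil raised genes of cyclic AMP signalling and the cytokine genes Il6 and Lif, and lowered fewer genes, the chemokine genes Ccl12 and Ccl4 among them. The interleukin gene Il6 rose by 2.60 (SE 0.38, adjusted p = 0.011), a 6.08-fold rise, from a mean log2 value of 6.38 ± 0.47 (SD, n = 3) to 8.98 ± 0.75 (SD, n = 3). The nuclear receptor gene Nr4a1, an immediate early gene, rose by 2.46 (SE 0.20, adjusted p = 0.000341). Other large rises were Rorb (1.70), an orphan nuclear receptor gene, Srgn (1.58), which encodes the proteoglycan core serglycin, Tfpi2 (1.26), a protease inhibitor gene, Pde4b (1.24), which encodes a phosphodiesterase that degrades cyclic AMP, and Lif (1.19), a cytokine gene. Nfil3 (1.14), Areg (1.11), which encodes the EGF receptor ligand amphiregulin, and Phlda1 (1.09) completed the 10 largest. The largest fall was that of the chemokine gene Ccl12, by −1.62 (SE 0.11, adjusted p = 0.000118), from 8.41 ± 0.09 (SD, n = 3) to 6.79 ± 0.13 (SD, n = 3). C3ar1 (−0.90), which encodes a complement receptor, the chemokine gene Ccl4 (−0.76), Lbh (−0.77), Tnfsf15 (−0.65), Tnf (−0.55), Camkk2 (−0.54), Hivep3 (−0.46) and the receptor kinase gene Axl (−0.37) also fell.

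In the list of cyclic AMP and CREB targets, 6 of 17 measured members rose with alprostadil, none fell and 11 did not pass (9 rose adjusted over the list alone, and 10 with the replicate number as a block). Those that rose were Nr4a1, Pde4b, Pde4d (0.84), Crem (0.49), Areg and Ppargc1a. The list's median was 0.49, and limma's camera called it up (adjusted p = 7.5e-21), also with an estimated correlation (adjusted p = 0.000171). Of 26 measured wound growth factors and proteases, 4 rose with alprostadil and none fell (adjusted p = 4.36e-05 by camera, adjusted p = 0.055 with an estimated correlation). These were Il6, Areg, the interleukin gene Il11 (0.77) and the angiogenic factor gene Vegfa (0.73). Adjusted over the list alone, 9 rose and 1 fell, and with the block 7 rose and 1 fell. Vegfa was also the member that rose among 15 genes of glycolysis and hypoxia, with 14 not passing (median 0.11, adjusted p = 0.00208, and adjusted p = 0.055 with an estimated correlation). Among 30 targets of MEK and ERK, Lif, Phlda1 and Ier3 (0.59) rose and 27 did not pass. That list's median was 0.02 and its mean 0.12 (adjusted p = 0.00375, and adjusted p = 0.363 with an estimated correlation). Adjusted over the list alone, 6 rose, and with the block 5.

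No member of the DNA replication list passed for alprostadil, and all 27 measured members had values below 0, from −0.43 to −0.07 (median −0.21, camera adjusted p = 3.79e-08). Of 28 mitosis genes, 27 did so as well, with no member passing (median −0.18, adjusted p = 4.3e-05). Both calls were lost with an estimated correlation, with adjusted p = 0.400 for replication and adjusted p = 0.546 for mitosis, and the mitosis call was lost without vehicle replicate 2 (median −0.07, adjusted p = 0.0834). Without that array the replication median was −0.10. The dermal papilla list (median 0.08, adjusted p = 0.00772), the dermal precursor list (median 0.06, adjusted p = 0.038) and the smooth muscle and myofibroblast list (median −0.11, adjusted p = 0.038) were called with no member passing over all genes. With the block, 4 dermal papilla genes and 1 dermal precursor gene rose and 2 smooth muscle genes fell. With an estimated correlation they gave adjusted p = 0.169, adjusted p = 0.356 and adjusted p = 0.169. All 3 lost their calls without vehicle replicate 1 (adjusted p = 0.0926, 0.145 and 0.0992) and without alprostadil replicate 3 (adjusted p = 0.0566, 0.312 and 0.0725), the dermal precursor list also without vehicle replicate 2 (adjusted p = 0.0857) and the smooth muscle list without alprostadil replicate 2 (adjusted p = 0.380). The dermal precursor median shrank to 0.0024 without alprostadil replicate 3, and the smooth muscle median to −0.050 without alprostadil replicate 2. The macrophage and leukocyte markers, set beside the chemokine genes, had a median of 0.06 and none of 15 passed. The other 18 lists, in which Axl was the only member that passed, were not called either, with medians of all 19 lists from −0.12 to 0.11 and a lowest adjusted p of 0.178.

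In all, 53 genes changed with alprostadil, 44 higher and 9 lower. With the replicate number as a block, 257 changed, 160 higher and 97 lower, among them all 53. Leaving out vehicle replicate 2 gave 30 genes, vehicle replicate 3 gave 32, alprostadil replicate 1 gave 34 and alprostadil replicate 2 gave 32. Of the 24 named genes that passed, Nr4a1, Rorb, Tfpi2, Pde4b, Pde4d, Phlda1, Vegfa, Ccl12 and C3ar1 passed in every alternative run for them. With the replicate block and all arrays, all 24 kept their calls. The runs without an array were made without the block, so differences between replicate numbers count as spread in them. They were not repeated with the block. Il6 did not pass without vehicle replicate 2 (adjusted p = 0.0561), vehicle replicate 3 (adjusted p = 0.0601), alprostadil replicate 1 (adjusted p = 0.0528) or alprostadil replicate 2 (adjusted p = 0.0714), and Tnf, Hivep3, Axl, Camkk2 and Lbh did not pass when any of the 6 arrays was left out, with adjusted p up to 0.229, 0.257, 0.165, 0.105 and 0.151. Areg and Nfil3 did not pass without vehicle replicate 1, vehicle replicate 2, vehicle replicate 3, alprostadil replicate 1 or alprostadil replicate 2 (adjusted p from 0.106 to 0.154 for Areg and from 0.0519 to 0.120 for Nfil3). Il11 did not pass without vehicle replicate 1, 2 or 3 or alprostadil replicate 1 or 3 (adjusted p from 0.0510 to 0.154). Crem did not pass without vehicle replicate 2 or 3 or alprostadil replicate 1 or 2 (adjusted p from 0.0764 to 0.0960), and Ier3 without the same arrays or alprostadil replicate 3 (adjusted p from 0.0756 to 0.102). Tnfsf15 did not pass without vehicle replicate 1 or 2 or alprostadil replicate 1 or 3 (adjusted p from 0.0510 to 0.0620), and Ccl4 without alprostadil replicate 1 (adjusted p = 0.0620) or 2 (adjusted p = 0.0626).

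**Figure D1:**
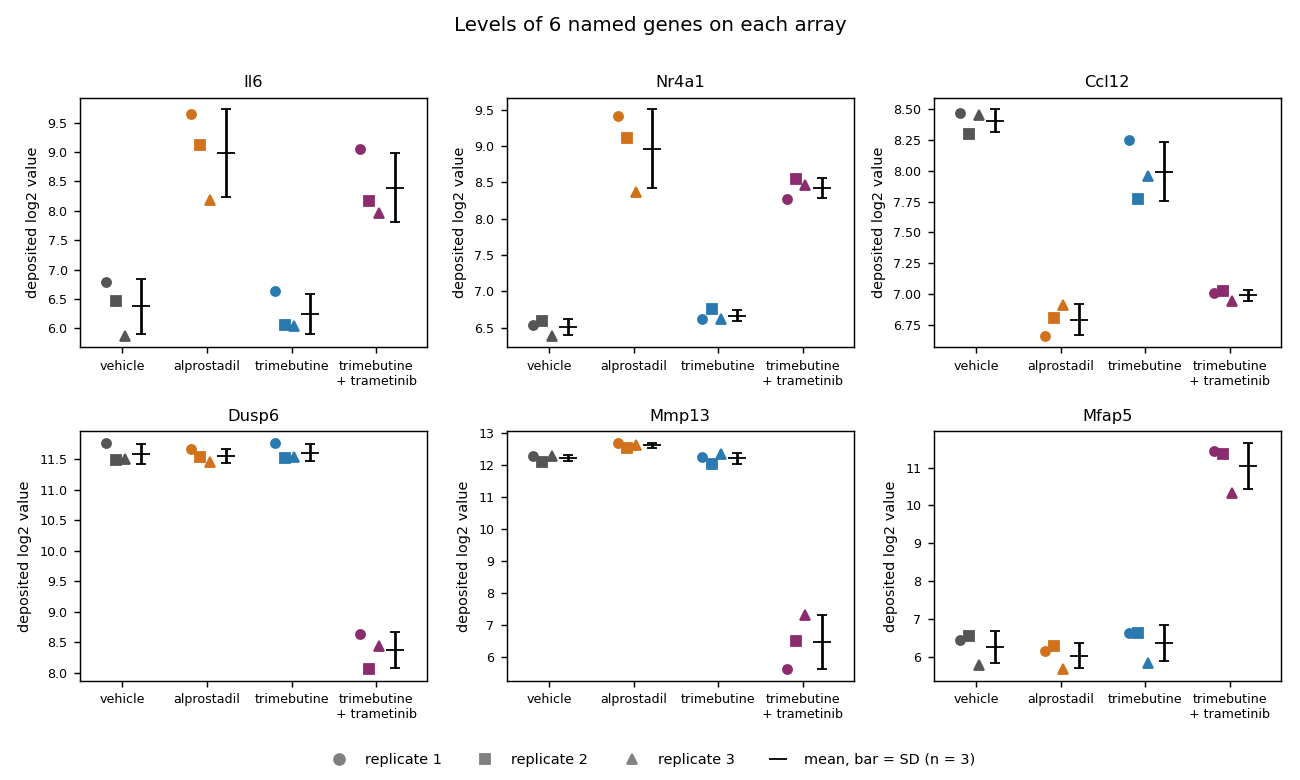
Deposited log2 values of Il6, Nr4a1, Ccl12, Dusp6, Mmp13 and Mfap5 on each of the 12 arrays, by treatment, with each panel on its own axis that does not start at 0; symbols give the replicate number, the dash is the mean and the bar the SD (n = 3). Ccl12 lay at 8.30 to 8.47 with vehicle and at 6.66 to 6.91 with alprostadil, and the mean of Mmp13 was 12.22 with trimebutine and 6.46 with trametinib added.

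Trimebutine alone was compared with vehicle to see what this drug changes at the same dose and time. No single gene passed, and the members of the MEK and ERK target list lay from −0.11 to 0.12, with a median of 0.003. The genes with the smallest p-values did not pass. They were Scnn1b (0.39), a sodium channel subunit gene, Kera (0.26), Potem (0.30), Qrfprl (0.31) and Pik3cd (0.26) on the higher side, and Adam4l1 (−0.24), Tead4l1 (−0.42), Ptchd1 (−0.28), Spata1 (−0.34) and Ccl12 (−0.41) on the lower side, all with adjusted p = 1.00. Across all genes the trimebutine differences had an SD of 0.0704, beside a median SE of 0.0867, or 0.0722 with the replicate block.

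The cholesterol synthesis list was the only one of 28 lists called for trimebutine. Its median was 0.10 with all 16 members above 0 and none passing (camera adjusted p = 4.19e-10), and the call was lost with an estimated correlation (adjusted p = 0.871). The MEK and ERK target list was not called (adjusted p = 0.993), and its test pointed below 0 while its median and its mean of 0.003 lay above. The cyclic AMP list (median 0.03), the mitosis list (−0.04), the replication list (−0.03) and the other 23 lists were not called, with a lowest adjusted p of 0.364. The count of changed genes was 0 by limma, also with the replicate block, where 252 genes had an unadjusted p under 0.05. Without the block 143 did.

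Trametinib was added to trimebutine to see what MEK inhibition changes in cells that also received trimebutine. The combination lowered cell cycle genes, targets of ERK signalling and the metalloproteinase genes Mmp13, Mmp3, Mmp10 and Mmp9, and raised genes of the extracellular matrix and of the ATF4 stress response. Against trimebutine alone, the collagenase gene Mmp13 fell by −5.75 (SE 0.30, adjusted p = 1.41e-07), from 12.22 ± 0.17 (SD, n = 3) to 6.46 ± 0.85 (SD, n = 3). With 1 of these last arrays (5.60) under the low-signal limit of 5.83, the size of that fall may be understated. That limit is a filter and not a measured floor, so this was not tested. The stromelysin genes Mmp3 (−5.55) and Mmp10 (−3.74) and the gelatinase gene Mmp9 (−3.36) fell too. Other large falls were Car2 (−3.44), a carbonic anhydrase gene, Sgo2 (−3.30), which protects centromeric cohesin, Dusp6 (−3.23), which encodes an ERK phosphatase induced by ERK itself, Top2a (−3.15), the ribonucleotide reductase gene Rrm2 (−3.12) and Bmp2 (−3.11), a bone morphogenetic protein gene. The largest rise was that of Mfap5, which encodes a microfibril protein, by 4.67 (SE 0.32, adjusted p = 9.98e-07). This rise may be understated too, since the lowest trimebutine array of Mfap5 lay at that limit. It was followed by Sfrp2 (3.69), a secreted Wnt modulator gene, Pdgfd (3.57), a growth factor gene, Adgrd1 (3.16), Tubb3 (2.86), a tubulin gene used as a neuronal marker, Adamts5 (2.74), an aggrecan-cleaving protease gene, the chemokine receptor gene Ackr3 (2.70), the water channel gene Aqp1 (2.63), Ccdc80 (2.61) and Cd55 (2.61), a complement regulator gene.

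All 28 measured mitosis genes fell when trametinib was added (median −2.26, camera adjusted p = 2.86e-28, and adjusted p = 0.112 with an estimated correlation), with Top2a, Ndc80 (−2.60), Kif11 (−2.49) and Nuf2 (−2.31) among them. Of 27 DNA replication genes, 26 fell (median −1.27, adjusted p = 2.41e-19, and adjusted p = 0.163 with an estimated correlation), including Tyms (−1.97) and Mcm4 (−1.39). Of 30 MEK and ERK targets, 20 fell, 2 rose and 8 did not pass (median −0.73, adjusted p = 6.76e-09, and adjusted p = 0.112 with an estimated correlation). Dusp6, Dusp5 (−3.00), Spry4 (−2.01) and Fosl1 (−1.71), which encode feedback inhibitors of the pathway and an AP-1 subunit, had the smallest p-values, and the 2 that rose were Fos and Spry2. Of 15 p53 targets and senescence genes, 9 fell and 2 rose (median −0.43, adjusted p = 0.00124, and adjusted p = 0.294 with an estimated correlation). Those that fell included the p53 inhibitor gene Mdm2 (−1.02) and the cell cycle inhibitor genes Cdkn2a (−1.43) and Cdkn2b (−1.05), and those that rose were the inhibitor genes Cdkn1b and Cdkn1c.

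Of 29 extracellular matrix genes, 20 rose, 1 fell and 8 did not pass with trametinib added (median 0.56, adjusted p = 9.14e-09, and adjusted p = 0.112 with an estimated correlation). Besides Mfap5, the fibrillin gene Fbn1 (1.21) and the collagen genes Col12a1 (1.36) and Col3a1 (0.97) rose, and the metalloproteinase inhibitor gene Timp1 fell. The gelatinase gene Mmp2, a member of this list, rose, unlike the 4 metalloproteinase genes above. Of 21 genes of ATF4 and the unfolded protein response, 18 rose and none fell (median 0.74, adjusted p = 3.55e-08, and adjusted p = 0.116 with an estimated correlation), with Atf5 (1.85), Trib3 (1.38), Atf3 (1.34) and Ddit3 (0.74) as examples. Among 12 smooth muscle and myofibroblast genes, 6 rose and none fell (median 0.44, adjusted p = 0.00429, and adjusted p = 0.112 with an estimated correlation), including the actin-binding protein gene Tagln (2.37) and the myosin light chain gene Myl9 (1.19). The wound growth factors and proteases split, with 13 of 26 falling and 6 rising (median −0.45, adjusted p = 0.00525, and adjusted p = 0.145 with an estimated correlation). The falls were led by the 4 metalloproteinase genes above, and those that rose were Il6, Fgf7, Inhba, Tgfb3, Plat and Cxcl12.

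The remaining 20 lists were not called for the addition of trametinib (lowest adjusted p = 0.191). Members of several went both ways. Among 17 cyclic AMP targets 6 rose, including Nr4a3 (2.42) and Dusp1 (0.80), and 4 fell, including the prostaglandin synthase gene Ptgs2 (−2.72) and Gem (−1.49), and the list's median (−0.04) and mean (0.07) differed in sign. Of 23 receptor tyrosine kinase genes 6 rose, such as Ephb3 (1.46), and 5 fell, such as Met (−1.18) and Pdgfra (−0.79). In the dermal precursor and neural crest list 4 of 24 rose, including Prrx2 (1.30) and Twist2 (0.83), and 7 fell, including Lrig1 (−1.09) and Dlk1 (−0.58). In the dermal papilla list 3 of 17 rose, including Bmp6 (2.14) and Fgf7 (1.69), and 2 fell, Wnt5a (−1.45) and Fgf10 (−1.08). Of 12 MAP kinase cascade genes 4 rose and 2 fell, all by less than 0.5. The interferon list had 3 of 14 members rising and 5 falling (median 0.01, mean −0.11), the glycolysis and hypoxia list 1 of 15 rising and 5 falling, the BMP and SMAD list 1 of 11 rising and 4 falling, the Wnt list 0 of 13 rising and 2 falling (median 0.06, mean −0.12), and the Notch list 1 of 11 rising and 2 falling. Of 16 cholesterol synthesis genes 5 rose and 1 fell. With the block, 2 Wnt targets rose, 2 genes of glycolysis and hypoxia rose and 7 fell, 4 Schwann and neural genes rose and 2 fell, and 2 extracellular matrix genes fell. The count of extracellular matrix genes that fell with the block was also 2 against vehicle. Of 9 housekeeping genes 1 rose and 3 fell, by at most 0.41 in size.

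Markers of other cell types were also followed when trametinib was added. The Schwann and neural list had 3 of 12 members rising (Tubb3, Ncam1 and Pmp22) and 1 falling, while 1 of 4 melanocyte genes and 1 of 7 endothelial genes rose and none of 11 keratinocyte genes passed. Of 11 adipocyte genes, Lpl (1.93) rose (median 0.35, adjusted p = 0.361). With the replicate block 10 rose and 1 fell, and that list was called up (camera adjusted p = 0.0102). Without the block it had adjusted p = 0.761 with an estimated correlation, which was 0.849 between its members. Differences between replicate numbers enter that correlation, and it was not estimated with the block, so it does not bear on the call with the block. In the macrophage and leukocyte list C1qa rose (0.52) and Cd68 fell (−1.03) among 15. With the block 5 rose and 3 fell, and the list was still not called (adjusted p = 0.981). The opioid receptor and ion channel list had 1 of 7 members rising and 1 falling.

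Against trimebutine alone 4556 genes changed, 2295 higher and 2261 lower, and 235 of the higher and 420 of the lower genes differed at least 2-fold. Against vehicle 4768 genes changed with the combination, 2383 higher and 2385 lower. The same metalloproteinase genes were among the largest falls, with Mmp13 at −5.76. Mfap5 was at 4.78, and both sizes may be understated for the same reason as above. The called lists had the same directions, and none of the 9 was called with an estimated correlation (lowest adjusted p = 0.115), while fry called all 9. Against trimebutine fry called all 8 lists that camera called. Of the 9 lists, camera called the cholesterol list up only in the comparison with vehicle (median 0.15, adjusted p = 0.00703, and adjusted p = 0.608 with an estimated correlation). Both comparisons called 2052 genes higher and 2129 lower, none in opposite directions. They share the 3 arrays of the combination, so these calls are not independent. The even division into higher and lower genes depended on the scaling, since with the arrays centred on their medians 1787 were higher and 2350 lower against trimebutine, and 1746 and 2547 against vehicle. No array held trametinib alone, so its effect without trimebutine is not separated here.

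**Figure D2:**
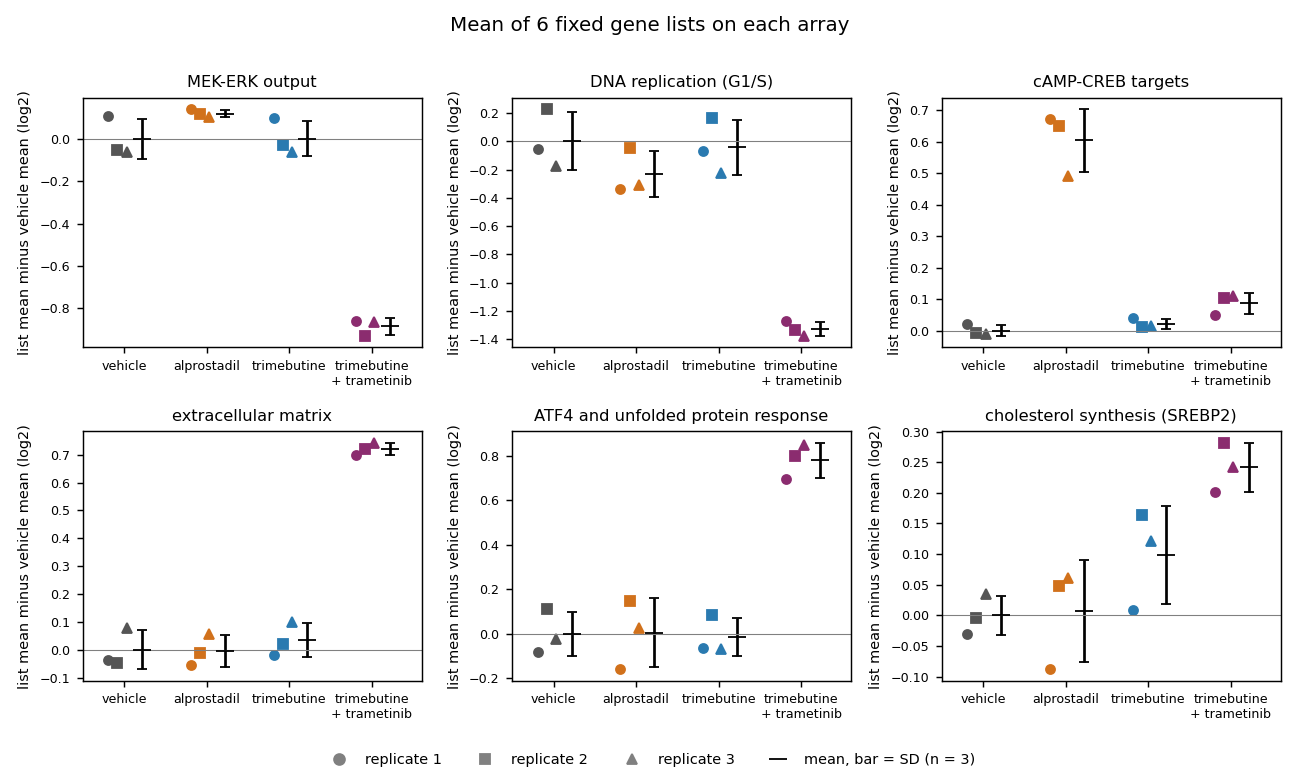
Mean log2 value of the measured members of 6 fixed gene lists on each of the 12 arrays, minus the mean of the 3 vehicle arrays, by treatment, with each panel on its own axis; symbols give the replicate number, the dash is the mean, the bar the SD (n = 3) and the grey line 0. The cyclic AMP list lay at 0.49 to 0.67 on the alprostadil arrays and at 0.01 to 0.04 on the trimebutine arrays, and the MEK and ERK list lay at −0.93 to −0.86 with trimebutine and trametinib.

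Trimebutine and alprostadil were also compared directly at the same dose and time. The largest differences on the side lower with trimebutine were Il6 (−2.73, SE 0.38, adjusted p = 0.00743), Nr4a1 (−2.30), Rorb (−1.69), Srgn (−1.57), Tfpi2 (−1.48), Phyhipl (−1.37), Lif (−1.25), Pde4b (−1.22), Giot1 (−1.22) and Nfil3 (−1.19), of which Phyhipl alone had not passed between alprostadil and vehicle (adjusted p = 0.0501). That comparison shares the alprostadil arrays with this one, so their agreement is in part built in. Areg and Ppargc1a, which rose with alprostadil, did not pass here (adjusted p = 0.074 for Areg and 0.0535 for Ppargc1a) and passed with the replicate block (adjusted p = 0.0023 and 0.0178). The 7 genes higher with trimebutine were Ccl12 (1.20, SE 0.11, adjusted p = 0.000926), C3ar1 (0.87), Lbh (0.79), Ccl4 (0.64), Tnfsf15 (0.64), Camkk2 (0.53) and Axl (0.39). The cyclic AMP list was lower with trimebutine, with 4 of 17 members falling (median −0.51, camera adjusted p = 1.43e-18, and adjusted p = 0.000265 with an estimated correlation), and 10 fell with the block. The glycolysis and hypoxia list was lower as well (median −0.13, adjusted p = 8e-05, and adjusted p = 0.022 with an estimated correlation), with 1 member falling, or 2 with the block. The wound list was lower, with Il6, Il11 and Vegfa falling (median −0.13, adjusted p = 6.08e-05, and adjusted p = 0.0557 with an estimated correlation), and with the block 9 fell and 1 rose. The DNA replication list (median 0.18, adjusted p = 5.5e-05, and adjusted p = 0.663 with an estimated correlation) and the mitosis list (median 0.15, adjusted p = 0.00358, and adjusted p = 0.786 with an estimated correlation) were higher with no member passing. The dermal papilla list (median −0.07, adjusted p = 0.0368, and adjusted p = 0.433 with an estimated correlation) and the dermal precursor list (median −0.04, adjusted p = 0.0477, and adjusted p = 0.478 with an estimated correlation) were lower with no member passing. With the block 4 and 2 of their members fell, 1 replication gene rose, and the dermal precursor list lost its call (adjusted p = 0.0808). The cholesterol list was higher with no member passing (median 0.07, adjusted p = 0.00204, and adjusted p = 0.575 with an estimated correlation). In the MEK and ERK list 3 members fell, its median was 0.0003 and its mean −0.12, and camera called it down (adjusted p = 0.00881, and adjusted p = 0.566 with an estimated correlation), and 6 fell with the block. The other 19 lists were not called. In all 52 genes differed, 7 higher and 45 lower with trimebutine, and 342 with the replicate block, 136 higher and 206 lower. Without alprostadil replicate 2 the count was 33 and without trimebutine replicate 2 it was 29.

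Several of these calls were lost when 1 array was left out. Lbh, Ccl4 and Axl did not pass when any of the 6 arrays was left out (adjusted p up to 0.130, 0.164 and 0.124). Their differences stayed at 0.75 to 0.85, 0.59 to 0.70 and 0.35 to 0.41. The sizes thus rested on no single array, while each call needed all 6 arrays. With the replicate block all 23 named genes that passed kept their calls. Crem and Camkk2 did not pass without any 1 of the alprostadil arrays or trimebutine replicate 1 or 2 (adjusted p up to 0.126 and 0.119), and Phyhipl without any 1 of the alprostadil arrays or trimebutine replicate 2 or 3 (adjusted p up to 0.174). Nfil3 did not pass without alprostadil replicate 1 or 2 or trimebutine replicate 1 or 3 (adjusted p up to 0.102), Tnfsf15 without alprostadil replicate 1 or 3 or trimebutine replicate 1 or 2 (adjusted p up to 0.0829), and Il6 without alprostadil replicate 2 (adjusted p = 0.0507) or trimebutine replicate 2 (adjusted p = 0.0550). Ccl12, C3ar1, Nr4a1, Rorb, Tfpi2, Lif, Pde4b and Giot1 passed in every alternative. Without trimebutine replicate 2 the lists of mitosis (adjusted p = 0.768), replication (adjusted p = 0.0984), dermal precursor (adjusted p = 0.336), dermal papilla (adjusted p = 0.0572) and cholesterol synthesis (adjusted p = 0.0693) lost their calls. Mitosis (adjusted p = 0.168) and cholesterol (adjusted p = 0.0804) lost theirs without alprostadil replicate 1, dermal papilla without alprostadil replicate 2 (adjusted p = 0.0676), and dermal precursor and papilla without alprostadil replicate 3 (adjusted p = 0.321 and 0.143) or trimebutine replicate 1 (adjusted p = 0.0640 and 0.302). The dermal precursor median turned to 0.0079 without alprostadil replicate 3, and the dermal papilla median to 0.0060 without trimebutine replicate 1. The mitosis median shrank to 0.028 without trimebutine replicate 2. The MEK and ERK list lost its call without trimebutine replicate 3 (adjusted p = 0.132).

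Among the known targets of the drugs, 4 prostanoid receptor genes changed when trametinib was added. Against trimebutine alone, the prostaglandin E receptor gene Ptger3 rose by 2.30 (SE 0.38, adjusted p = 0.000708), Ptger4 by 0.50 and the prostaglandin F receptor gene Ptgfr by 0.58, while the prostacyclin receptor gene Ptgir fell by −1.11 (SE 0.07, adjusted p = 3.61e-07). Of 13 measured prostanoid receptor and metabolism genes 3 rose and 4 fell, the latter with Ptgs2, Ptgis and the prostaglandin transporter gene Slco2a1 (−2.81). Its median was 0.03 and its mean −0.27, and the list was not called (adjusted p = 0.539). The MEK genes themselves moved little, with Map2k1 at −0.24 and Map2k2 at 0.25, both passing. With alprostadil none of the prostanoid receptor genes passed, and Ptgfr (0.53, adjusted p = 0.132) passed with the replicate block (adjusted p = 0.0105). Ptger1, Ptger2 and Tbxa2r did not pass when trametinib was added. The delta and kappa opioid receptor genes Oprd1 (0.05) and Oprk1 (0.10) and the nociceptin receptor gene Oprl1 (0.12) did not pass there either, and the mu opioid receptor gene Oprm1 was below the low-signal limit on average.

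Over the 4 groups together, 4436 genes differed by limma's moderated F test. Fold changes of alprostadil and of trimebutine against the shared vehicle arrays correlated at r = 0.20 across genes (Spearman's rho = 0.23), which are not independent replicates. Leaving out single arrays moved this r widely, as given under the processing. Unchanged groups simulated against shared vehicle arrays gave r = 0.50, from 0.48 to 0.52 in 100 simulations. The covariance was 0.00206 beside a simulated 0.00341, and 57.2% of genes had the same sign beside a simulated 66.7%. Fold changes of trimebutine and of adding trametinib, which share the trimebutine arrays with opposite sign, correlated at r = 0.01 (rho = −0.03) beside a simulated r of −0.50. Their covariance was 0.000279 beside a simulated −0.00342, and 49.1% of genes had the same sign beside 33.4%. The simulated groups were all unchanged, so their fold changes have equal spread. The real fold changes had an SD of 0.143 with alprostadil, 0.0704 with trimebutine and 0.465 with trametinib added. The simulated r and same-sign shares are therefore no fair reference, and no conclusion is drawn from the distance to them. No call of trimebutine existed to overlap with any other list. The 3 shared arrays are too few to be divided between the comparisons with at least 2 in each.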

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

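The tests of the explanations below were chosen after the results were seen, except the regroupings of arrays. The rule of the comparison with random lists is recorded as written beforehand, but the list it was applied to was picked from the results. The 95% intervals replaced a limit of 2 standard errors after the values were seen, and under that limit the cholesterol and mitosis differences would have stood apart from 0. Features without a single gene symbol, which entered no comparison above, also changed. Of 9611 such features above the low-signal limit, 6 were higher with alprostadil, 949 changed with the combination against vehicle, 762 changed when trametinib was added to trimebutine, and 6 differed between trimebutine and alprostadil.

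The cholesterol synthesis list was higher with trimebutine while no gene passed. Its median lay above those of all 10000 random lists matched on brightness (percentile 100). The list was picked because camera had already called it against the other genes, and random genes do not vary together as these do. This comparison therefore cannot decide whether it is a chance list of equally bright genes. The list was also higher in trimebutine than in alprostadil (median 0.069, called at the preset correlation only, adjusted p = 0.575 with an estimated one), which argues against low vehicle arrays as the whole source. Members that vary together between cultures may still account for it. The difference of list means from vehicle was above 0 in 3 of 3 replicate numbers, with a mean of 0.10 and a 95% interval from −0.06 to 0.26, while that from alprostadil had a mean of 0.09 and an interval from 0.02 to 0.16.

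The cell cycle lists were lower with alprostadil while no member passed. Without alprostadil replicate 1, the array with the highest median, the replication median was −0.16 and still called at the preset correlation, so that array is not the whole source, but the call over all arrays was lost with an estimated correlation (adjusted p = 0.400). Without vehicle replicate 2 the medians were −0.098 for replication and −0.071 for mitosis, whose call was lost (adjusted p = 0.0834). If a replicate number marks an isolate, as the pairing of the arrays was read, growth rates of isolates cancel and the variation of single cultures remains. The difference of list means within replicate numbers was −0.23 for replication (95% interval from −0.43 to −0.03) and −0.17 for mitosis (−0.48 to 0.14). With 3 differences and an interval for mitosis that includes 0, single cultures that grew at different rates are left open, and so is a lower rate of cell division with alprostadil, which was not tested.

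Ccl12, Ccl4, Tnf and Tnfsf15 fell with alprostadil by a median of −0.71. Fewer macrophages, a type of cell that makes such factors, would lower their other abundant transcripts alike. The macrophage and leukocyte list had a median of 0.059, with an SD of 0.12 over its 15 members, and its mean difference within replicate numbers was 0.04 (95% interval from −0.42 to 0.49). This argues against a loss of all macrophages alike as the source. C3ar1 (−0.90), a receptor gene of such cells, fell too, and with the replicate block so did Adgre1 (−0.83), Clec4a3 (−0.74) and Ccl3 (−0.74), so fewer cells of a part of the macrophages, or a change within them, may remain and was not tested.

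Whether chance can be excluded was asked by regrouping the arrays. For each pair of groups there are 10 ways to divide 6 arrays, too few for a share under 0.05. Against real counts of 53 for alprostadil, 4768 and 4556 for the combination against vehicle and against trimebutine, and 52 for trimebutine against alprostadil, the highest other division gave 0 genes, and 1 of 10 divisions (the real one) gave as many. For trimebutine against vehicle all 10 gave 0. Of the 10, 4 part all 3 replicate numbers, the real one included, and the others among those also gave 0. For the 4 groups, 2 of 100 drawn divisions out of 15400, the real one included, gave at least the 4436 genes of the real one. The higher one, with 5326 genes, was the 1 other draw that kept the arrays with trametinib together, and the highest of the rest gave 7. The rank of the real division thus follows from how rarely a draw keeps those arrays together. The draws cannot tell whether vehicle, alprostadil and trimebutine differ by more than a chance division. They also regrouped arrays across replicate numbers and used the fit without the block.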

How the results depend on the processing

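The counts for the combination, 4768 and 4556, stayed within 1.5 times in every alternative except a 1.5-fold limit, which gave 1495 and 1460, and 1504 for the 4436 genes of the F test. The alprostadil count of 53 became 84 with array weights, 81 at adjusted p under 0.1, 29 with only the 6 arrays compared and 35 of all features. The trimebutine against alprostadil count of 52 became 101, 99, 29 and 34. The replicate block, which follows the pairing of the numbers, gave 257 and 342. The trimebutine count was 0 in all. Leaving out each array gave 30 to 42 genes for alprostadil, 29 to 44 for trimebutine against alprostadil, 3811 to 4341 and 3677 to 4165 for the combination, and 3214 to 4321 for the F test. The cause of these moves was not tested.

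With an estimated correlation, 8 of the 9 called lists were lost for alprostadil, 7 of 9 for trimebutine against alprostadil and all for the combination. Among these were the lists of MEK and ERK targets (0.025 with alprostadil, −0.73 with trametinib added), mitosis (−0.18 and −2.26), replication (−0.21 and −1.27) and, for trimebutine, cholesterol (0.10). Some lists with an estimated correlation below 0 lost their calls too. Examples are smooth muscle with trametinib added (correlation −0.037) and glycolysis and hypoxia with alprostadil (−0.031). A lost call alone therefore does not show that the members vary together. With fry, the alprostadil lists of MEK and ERK targets (0.025), mitosis (−0.18) and replication (−0.21) and the cholesterol list (0.10) lost theirs. So did the dermal papilla and dermal precursor lists with alprostadil, and 6 of 9 lists for trimebutine against alprostadil (MEK and ERK targets, mitosis, replication, dermal papilla, dermal precursor and cholesterol). Fry kept all 9 lists of the combination against vehicle and all 8 against trimebutine. With alprostadil it kept 4 of 9, the lists of cyclic AMP, wound factors, glycolysis and hypoxia, and smooth muscle. Lists also lost calls with single arrays left out, up to 3 of 9 for alprostadil (without vehicle replicate 1 or alprostadil replicate 3) and 5 of 9 for trimebutine against alprostadil (without trimebutine replicate 2), and the wound list lost its call for the combination at the 50th percentile limit (adjusted p = 0.0846 against trimebutine and 0.0898 against vehicle). With alprostadil, camera lost the smooth muscle list at that limit (adjusted p = 0.0642), with quantile normalization again (0.0529) and with only 6 arrays (0.0787). It lost the dermal precursor list with no limit (0.0662) and over all features (0.0989). For trimebutine against alprostadil it lost MEK and ERK targets at the 50th percentile limit (0.0628). There the dermal papilla (0.0716) and dermal precursor (0.107) lists were lost over all features. The cyclic AMP list with alprostadil kept its call throughout. Leaving out arrays, medians ran from −0.02 to 0.11 for MEK and ERK targets, −0.24 to −0.071 for mitosis and −0.31 to −0.10 for replication with alprostadil, and from 0.07 to 0.14 for cholesterol with trimebutine.

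The trimebutine median of MEK and ERK targets, never called, had a test of the other direction with the 50th percentile limit (0.0029), quantile normalization again (0.011), median centring (−0.0034), array weights (−0.00010) and the replicate block (0.0029), and ranged from −0.060 to 0.048 with single arrays left out. The correlation of alprostadil and trimebutine was 0.38 over all features and 0.085 to 0.51 with single arrays left out. That of trimebutine and adding trametinib, 0.01, turned to −0.070 with no limit on signal, −0.0027 with quantile normalization again and −0.18 over all features, and ranged from −0.19 to 0.085 with single arrays left out; its sign is not settled. Moves of a correlation were judged against the SD over the single arrays left out.

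The block also called the adipocyte list up for the combination against vehicle (adjusted p = 0.00932, beside 0.693 with an estimated correlation and no block), and it changed no other list call beyond those in the results. Of the 24 named genes of alprostadil that passed, 9 passed in every alternative, as did 12 of 23 for trimebutine against alprostadil, 92 of 101 for trametinib added and 94 of 104 for the combination against vehicle. No named gene turned its direction.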

Other observations

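The tests in this part were chosen after the results were seen. In each of the 4 groups the arrays differed by replicate number in markers of other cells, and both lists below rose from replicate 1 to replicate 3. On the vehicle arrays the list means lay from −0.57 to 0.64 around their average for macrophage and leukocyte markers and from −0.58 to 0.60 for adipocyte markers. Relative to the vehicle mean, the macrophage list lay from −0.75 to 0.78 with alprostadil, −0.66 to 0.69 with trimebutine and −0.65 to 0.42 with the combination. The group means of the macrophage list on the other 9 arrays lay within −0.02 to 0.04 of the vehicle mean, and those of the adipocyte list lay at −0.11 with alprostadil, 0.02 with trimebutine and 0.46 with the combination.

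Alprostadil and trametinib, in comparisons that share no array, changed some of the same genes in both directions. Of the 44 genes raised by alprostadil, 15 rose when trametinib was added, among them Il6, Nr4a1, Crem, Nfil3 and Ppargc1a, where independent lists would share 7.41. As many, 15, fell, among them Vegfa, Phlda1, Rorb and Tfpi2, beside 7.30. Of the 9 genes lowered by alprostadil, 5 fell with trametinib added, Ccl12, Ccl4, Tnf, Camkk2 and Hivep3, beside 1.49, and 2 rose, C3ar1 and Tnfsf15, beside 1.51. With the replicate block, of 97 lowered genes 40 rose, beside 20.6, and 36 fell, beside 20.1, and of 160 raised genes 48 rose, beside 33.9, and 64 fell, beside 33.2. Across all genes these fold changes correlated at r = 0.02. Both comparisons take each gene's spread from the same fit, so genes with a small spread can pass in both. Independent lists are therefore not a full reference for the shared numbers.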
